A study of Mus musculus with 4 samples.

How the data were processed

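Total RNA from whole brains of mouse embryos at embryonic day 14.5 was labelled with biotin after amplification, per the labels' protocols, and hybridised to Affymetrix arrays of 1 colour. Of the 4 arrays, 2 came from control embryos and 2 from Sox4 and Sox11 double-knockout embryos, and groups and replicate numbers were taken from the sample titles. The authors deposited a table of probe set intensities on a linear scale, made with MAS5 version 5.0 per the submitters' processing notes. The genome build is not given in the sources used here, and no coordinates are printed. The mean of each array after trimming 2% at either end was 1000, so every array had been scaled to the same level before deposit. MAS5 scales arrays by 1 factor each, and a group-wide shift of most transcripts would be removed by this step. No detection calls were used, so a low signal is not called absent. No per-sample column of the table was left unused.

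The table held 45101 probe sets, of which 64 were array controls and were left out. Gene symbols came from the platform annotation supplied for the array: 34958 probe sets had 1 symbol, 932 had several and 9211 had none. Of those with 1 symbol, 34754 were matched by gene ID to a RefSeq gene table, and 0 symbols needed an update. Probe sets with several symbols or none were tested and counted but not named. A probe set whose identifier holds x or s can detect related transcripts, and values of close paralogs such as Lyz1 and Lyz2 or the protocadherin beta genes can share signal.

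Signals were transformed as log2(signal + 16), with no further normalization between arrays. Fold changes are on this scale, which understates the change of dim genes. Probe sets were kept where the mean log2 value over all 4 arrays lay above the 40th percentile of the 45037 non-control probe sets, a cutoff of 7.41 (signal 154.6), which left 27022. The comparison was knockout minus control in limma 3.58.1 under R 4.3.3, with lmFit, eBayes with a variance trend and Benjamini-Hochberg adjustment over the probe sets kept, at an adjusted p under 0.05. Residual degrees of freedom were 2 and the prior added 8.33. Rose, fell and changed refer to this threshold, and every adjusted p of a gene is from this fit unless another is named. SDs are of the signals of 2 arrays, and SEs are of the log2 change. Each gene took the value of its probe set with the highest mean, which gave 12489 genes. Of 5943 genes with several tested probe sets, 18 had at least 1 that rose and 1 that fell. The brightest probe set called 1716 of these genes, and for 904 of them at least 1 other was called in the same direction. Where the labels do not say how many embryos an array held, p-values measure the spread between these arrays only.

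The design, 27 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule named Sox4, Sox11, Sox12, Tead2, Tubb3, Dcx and Pou3f4, the 12 largest rises and 12 largest falls among genes past the threshold with separated groups and 1 symbol, and 2 to 4 members of each list by size of change. Other members, named to complete a count of 5 or fewer or as single features, were chosen after their values were seen. They are Nhlh1, Cntn2, Gng3, Grin2b, Myt1l, Myt1, Elavl2, Id4, Msi1, Cdh2, Mcm7, Emx1, Npy, Bcl2, Plk2, Dusp1, Btg2, Tead1, Gli3, Lgr5, Lef1, Pdgfra, Chl1, Ephb1, Mrc1, Pf4 and Csf1r. Several genes belong to more than 1 list, such as Slc17a6, Barhl2, Isl1 and Sox9. The lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, over the 26 lists with at least 5 measured members, with Benjamini-Hochberg adjustment over lists. Of these 26, 13 passed camera with the preset correlation and 0 with an estimated correlation, while 7 passed the directional test of fry and 26 its mixed test. The 7 were neuronal cytoskeleton, excitatory cortical neurons, midbrain, hindbrain and spinal neurons, astrocytes, microglia, mesenchyme and ribosomal proteins. The other lists called by camera's preset correlation had adjusted p of 0.0502 to 0.22 in the directional test of fry. These were the proneural, synaptic, ganglionic eminence, forebrain regional, cell cycle, endothelial and hypoxia lists. Neither fry test compares a list with other genes. The list of sex-linked genes had 4 measured members and no set test.

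Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, eBayes without trend and robust, a threshold of 0.1, each array left out in turn, the replicate number as a block, and the mean of a gene's probe sets. Leaving out genes of the sex chromosomes was added after the data were seen, as were the list counts given with single arrays left out. The steps were tested on simulated data of this comparison with 27022 probe sets, 200 of them changed. At 2 arrays per group, 0% of those changed 1.25-fold, 6% at 1.5-fold, 46% at 2-fold and 78% at 3-fold were recovered, and 7.143% of calls were false. The simulated arrays had a median fitted SD of 0.147, against 0.126 in the real ones. In the real comparison 23.2% of the probe sets changed, a far larger share than in the simulation. The Benjamini-Hochberg threshold is looser where more probe sets change, so the recovered shares are not estimates for the real data. In a simulation of 12489 genes with independent errors, a list of 18 genes was shifted. Camera gave it an adjusted p of 1.508e-15 with the preset correlation and 0.3108 with an estimated correlation. The estimated correlation thus missed a true shift with 2 arrays per group. A list or family that fails it is therefore not shown to be unchanged. Because the errors were independent, the simulation does not test the preset correlation where genes vary together.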

Results

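Gene expression was measured in whole brains of mouse embryos at embryonic day 14.5, on a mixed 129SvJ/C57Bl/6J background, with 4 Affymetrix arrays. The 2 control arrays came from embryos with floxed Sox4 and floxed Sox11 alleles, and the 2 double-knockout arrays from embryos that carried the same alleles with Brn4::Cre, a Cre recombinase driver named for the gene Pou3f4 (Brn4). Sox4 and Sox11 belong to the SoxC group of transcription factors, which act in newly formed neurons. The series title speaks of SoxC-regulated genes in the spinal cord, while all 4 sample labels name whole brain. The comparison asks how transcript levels differ between brains with and without the 2 genes. The labels call the arrays biological replicates and do not say whether an array held RNA of 1 embryo or of a pool, nor the sex of the embryos. Median signals were 287.6 and 262.6 on the control arrays and 263.7 and 269.2 on the knockout arrays. Log2 signals correlated across probe sets with r = 0.984 between the controls and 0.987 between the knockouts, against 0.960 to 0.963 between an array of each group. Probe sets are not independent replicates, so these r values describe the arrays only. The number of arrays limits the precision of every value given here.

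The targeted genes were examined first. All 6 Sox11 probe sets fell in the knockout, by 2.29-fold to 9.08-fold. The largest fall was at 1431225_at, from a signal of 9707 ± 2497 in controls to 1040 ± 94.8 in knockouts (SD, n = 2 each; log2 change -3.18 ± 0.15, SE; limma adjusted p = 2.8e-06). The brightest Sox11 probe set, 1436790_a_at, fell from 25774 ± 457 to 9899 ± 576 (log2 change -1.38 ± 0.07, adjusted p = 2.96e-06). The 8 Sox4 probe sets did not move together. Of the 6 bright enough to be tested, 4 fell by 2.13-fold to 6.48-fold, as at 1419156_at, which went from 14893 ± 313 to 2297 ± 310 (log2 change -2.69 ± 0.10, adjusted p = 8.21e-07). A single Sox4 probe set, 1419157_at, rose from 4799 ± 768 to 16953 ± 708 (log2 change 1.83 ± 0.10, adjusted p = 6.84e-06). The brightest, 1433575_at, read 35433 ± 869 and 37770 ± 697 (log2 change 0.09 ± 0.05, adjusted p = 0.242). The smallest Sox4 fall, at 1455867_at (log2 change -1.09), no longer passed without knockout 1 (-1.0, adjusted p = 0.063). Probe sequences were not used here, so it is unknown which of these probe sets lie in the deleted part, and a probe set outside it checks nothing. Both knockout arrays lay on the same side of both control arrays at all 12 tested probe sets of the 2 genes. Sox12, the third SoxC gene, did not pass at its brightest probe set (log2 change 0.23 ± 0.11, adjusted p = 0.171) and rose at 1439754_at (0.49 ± 0.13, adjusted p = 0.0251). Pou3f4, whose name the Cre driver carries, had a log2 change of -0.10 ± 0.15 (adjusted p = 0.682).

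**Figure D1:**
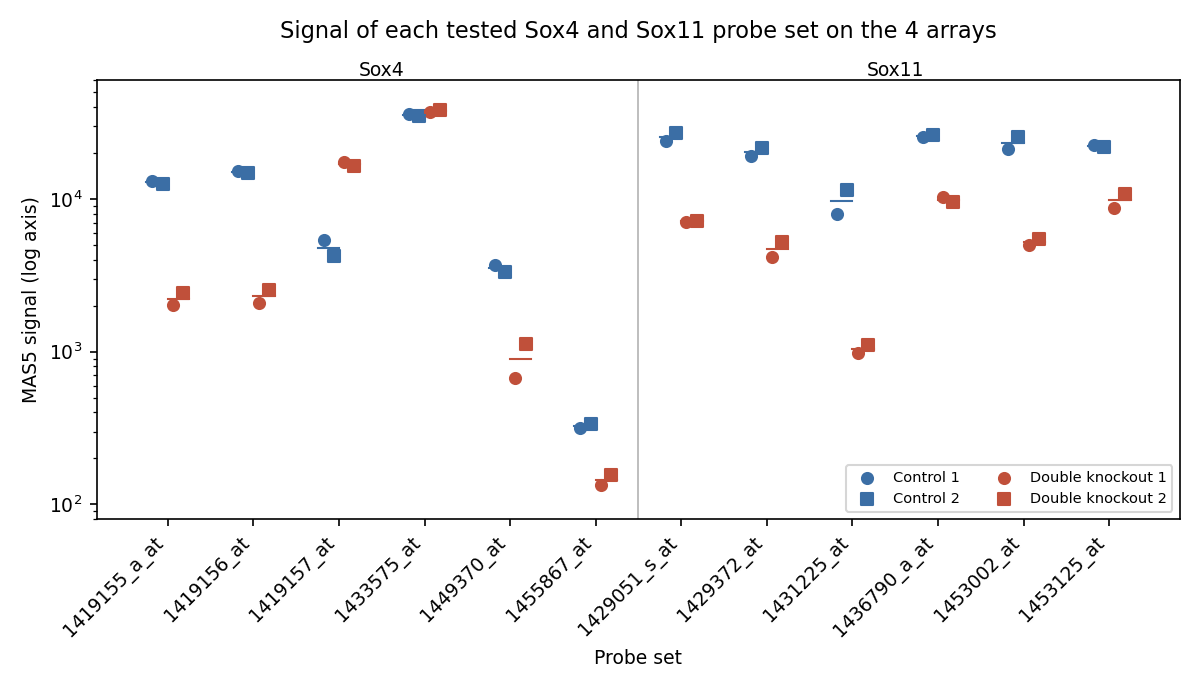
Signal (MAS5 units, log axis) of the 12 tested Sox4 and Sox11 probe sets on each of the 4 arrays, with short lines at the group means; circles and squares are replicates 1 and 2, blue is control and red is double knockout. All 6 Sox11 probe sets and 4 of 6 Sox4 probe sets were lower in the knockout, 1419157_at was higher, and 1433575_at differed by a log2 change of 0.09.

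Many genes differed between the genotypes. Of 27022 probe sets tested, 3152 rose and 3125 fell, together 6277 (23.2%), and 403 of those that rose and 447 of those that fell changed at least 2-fold. Counted by gene, with each gene read at its brightest probe set, 2032 of 12489 rose and 1376 fell, 274 and 172 of them at least 2-fold. Both knockout arrays lay on 1 side of both control arrays at 16989 probe sets (62.9%), where chance gives 33.3%. The number of changed probe sets differed with the array left out and with the model of the variance. It was 3132 without knockout 1, 3518 without knockout 2, 4780 without control 1 and 5422 without control 2, and 3114 when the prior variance had no trend with signal. Each of the 4 left-out fits sets a lone array against a pair, and the lone array is taken to vary like the pair.

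Among the genes with the largest rises were Trhr, the receptor of thyrotropin-releasing hormone, Mfap4, an extracellular matrix protein, and Tac2, a tachykinin neuropeptide. Trhr went from 238.5 ± 2.83 to 2097 ± 412 (SD, n = 2 each), a log2 change of 3.04 ± 0.16 (SE; limma adjusted p = 5.49e-06), Mfap4 rose by a log2 change of 2.91 ± 0.13 and Tac2 by 2.51 ± 0.18. Ptk2b (2.70), a tyrosine kinase, Acvr1c (2.18), an activin-type receptor, Mt2 (2.17), a metallothionein, Gcg (2.13), which encodes glucagon-family peptides, and Dnah6 (2.15), a dynein heavy chain, were also among the 12 largest rises. The remaining 4 were Mpeg1 (2.35), Ccl6 (2.29), C1qa (2.14) and Lyz1 (2.13), which are expressed by macrophages. The Lyz1 probe set carries a suffix for probes shared between transcripts and can also detect its paralog Lyz2. The largest fall was that of Gpc2, a cell-surface glypican of developing neurons, from 4175 ± 360 to 507 ± 65.4 (log2 change -3.00 ± 0.13, adjusted p = 1.53e-06). Cd1d1, an antigen-presenting molecule, fell by a log2 change of -2.41, Slco5a1, a transporter of the organic anion family, by -2.35, and B3gnt5, a glycosyltransferase of lacto-series lipids, by -2.07. The transcription factors Gata3 (-2.18), Zfp57 (-1.98) and Tfap2a (-1.96) fell, as did Tmem44 (-2.11), Macroh2a3 (-2.05), Pcdhb16 (-2.02), Arg2 (-2.02) and Slc27a2 (-1.96). The 12 largest rises spanned 4.38-fold to 8.23-fold and the 12 largest falls 3.89-fold to 8.02-fold, with adjusted p up to 0.00847. Of these 24 genes, Dnah6 had an adjusted p of 0.07 in limma without the variance trend. Tfap2a had another probe set that did not pass and whose change had the opposite sign.

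**Figure D2:**
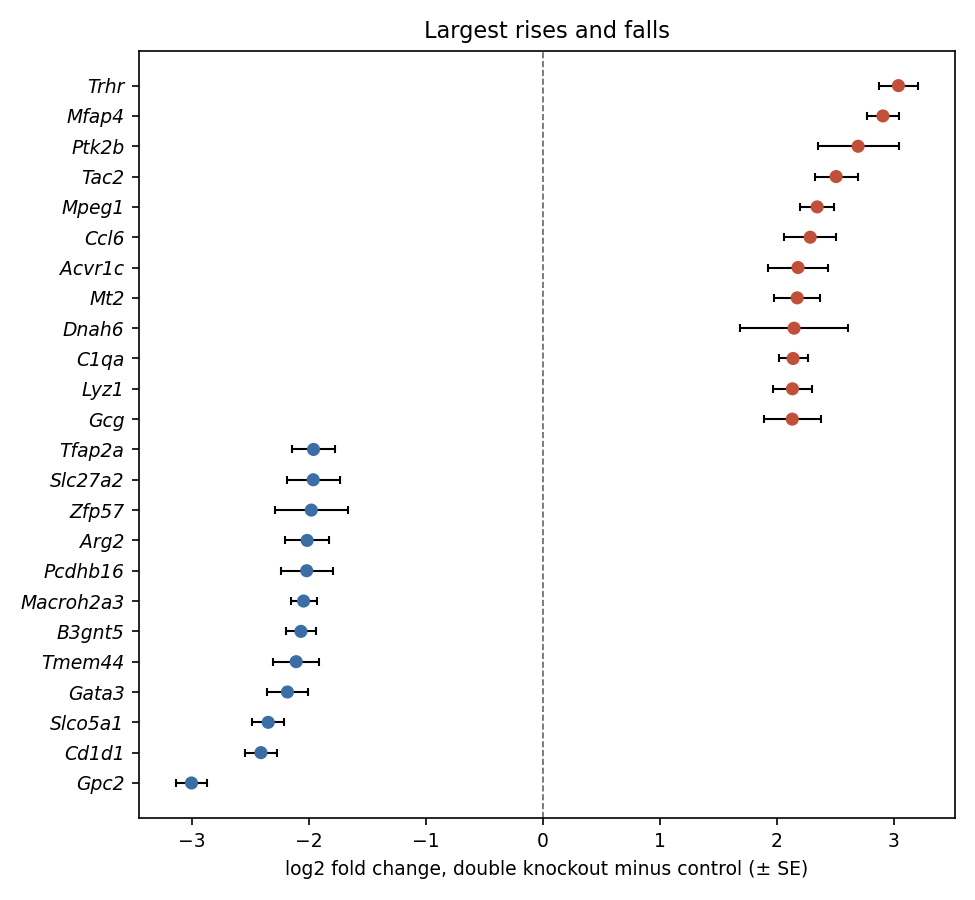
Log2 fold change (knockout minus control, on the log2(signal + 16) scale) of the 12 genes with the largest rise (red) and the 12 with the largest fall (blue); bars are SE from the limma fit over 2 arrays per group. Values run from 3.04 for Trhr to -3.00 for Gpc2.

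Genes of the neuronal cytoskeleton and of early neuronal differentiation fell. Of 35 measured, 19 fell, 3 rose and 13 did not pass (20 and 3 adjusted over the list alone), with a median log2 change of -0.26. Ina, an intermediate filament of neurons, fell by a log2 change of -1.02, Nhlh2, a transcription factor of young neurons, by -0.83, and Nsg1, a neuronal vesicle protein, by -0.75. Tubb3, a neuronal tubulin, went from 20498 ± 400 to 12195 ± 298 (SD, n = 2 each; log2 change -0.75 ± 0.06, SE; limma adjusted p = 6.59e-05). Dcx, a microtubule-binding protein of migrating neurons, went from 18396 ± 857 to 11073 ± 528 (-0.73 ± 0.07, adjusted p = 0.000119). The 3 that rose were Nhlh1 (0.71), Cntn2 (0.51) and Gng3 (0.47). Cntn2 averaged over its probe sets did not pass (0.31). None of the 3 passed without knockout 1 (0.77, 0.30 and 0.28), and Nhlh1 did not pass without knockout 2 (0.65) or control 2 (0.47) either. Map2 and Stmn1 did not pass at their brightest probe sets and fell at others. Dimmer probe sets of Dcx fell further (-1.16, -1.14 and -0.93), as did that of Nefl (-0.85, against -0.41 at its brightest). Those of Elavl4 changed less (-0.16 and -0.25, against -0.32). Whether the brightest probe sets were compressed was not tested. The set test camera gave the list an adjusted p of 4.63e-08 with the preset correlation and an adjusted p = 0.458 with an estimated correlation. Without the variance trend 7 fell and 0 rose, and without the signal filter 0 rose.

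Synaptic genes moved the other way. Of 25 measured, 11 rose, 1 fell and 13 did not pass (14 and 1 adjusted over the list alone), with a median log2 change of 0.24. Slc17a7, a vesicular glutamate transporter, rose by a log2 change of 1.23, Rab3a, a GTPase of synaptic vesicles, by 1.03, Syp, a synaptic vesicle membrane protein, by 0.89, and Cplx2, a regulator of vesicle fusion, by 0.67. Grin2b, an NMDA receptor subunit, fell by -0.40. The Slc17a7 call was lost without knockout 1 (1.25) and without knockout 2 (1.20), and that of Grin2b without knockout 1 (-0.53), knockout 2 (-0.28) or control 2 (-0.34). Syt1 rose at its brightest probe set (0.46) and fell at another (-0.54). Camera gave an adjusted p of 0.00306 with the preset correlation, and adjusted p = 0.458 with an estimated correlation. The number that rose was 7 without knockout 2, and 7 without the variance trend.

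Cell cycle genes rose. Of 37 measured, 25 rose, 1 fell and 11 did not pass (32 and 1 adjusted over the list alone), with a median log2 change of 0.46. Birc5 (survivin), a regulator of mitosis, rose by a log2 change of 0.88, Prc1, a cytokinesis protein, by 0.83, Aurkb, a mitotic kinase, by 0.78, and Mki67, a nuclear protein of cycling cells, by 0.76. Mcm7, a subunit of the replicative helicase, fell by -0.27. Camera gave an adjusted p of 1.9e-08 with the preset correlation, and adjusted p = 0.458 with an estimated correlation. The count that rose was 16 without control 2, 14 without knockout 1, 13 without knockout 2 and 8 without the variance trend. Aurkb alone of the 4 lost its call without control 2 (0.49), knockout 1 (0.67) or knockout 2 (0.89), and Mcm7 lost it without control 1 (-0.26), control 2 (-0.27) or knockout 2 (-0.22).

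Among proneural factors and genes of intermediate progenitors, 8 of 19 rose, 4 fell and 7 did not pass (9 and 4 adjusted over the list alone), with a median log2 change of 0.21. The largest rises were those of Mfap4 (2.91), Neurod4 (1.78), a proneural transcription factor, and Eomes (1.08), a transcription factor of intermediate progenitors. Those that fell were Atoh1 (-1.11), a proneural factor of the hindbrain, Myt1l (-0.57), Myt1 (-0.44) and Elavl2 (-0.25). The Atoh1 call was lost without knockout 1 (-1.09) or knockout 2 (-1.12), that of Myt1 without control 1 (-0.36) or knockout 2 (-0.31), and that of Elavl2 without control 1 (-0.26), control 2 (-0.24) or knockout 1 (-0.15). Camera gave an adjusted p of 0.0428, and adjusted p = 0.604 with an estimated correlation. The preset test did not pass without knockout 1 (adjusted p = 0.0643) or knockout 2 (adjusted p = 0.0505), and 5 genes rose without control 2. With control 1 left out 1 gene fell, and with either knockout array left out 2 fell. The counts were 5 that rose and 2 that fell without the variance trend, and 1 fell without the signal filter.

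The list of radial glia and neural progenitor genes was not called by camera (adjusted p = 0.307), and its median log2 change was 0.23. Of 24 measured, 10 rose, 4 fell and 10 did not pass (13 and 5 adjusted over the list alone). Lhx2 (0.87) and Sox3 (0.63), transcription factors of neural progenitors, and Nes (0.61), an intermediate filament of progenitors, rose. Prom1 (-0.77), a membrane glycoprotein, Id4 (-0.46), Msi1 (-0.41) and Cdh2 (-0.29) fell. Nes did not pass without knockout 1 (0.55), Msi1 without knockout 2 (-0.33), and Cdh2 without control 2 (-0.27) or knockout 1 (-0.22). Other Nes probe sets did not pass, and 5 genes rose without knockout 1. With no variance trend 3 genes rose and 1 fell.

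Genes that mark neurons of the midbrain, hindbrain and spinal cord fell. Of 29 measured, 15 fell, 2 rose and 12 did not pass (15 and 2 adjusted over the list alone), with a median log2 change of -0.58. Gata3, a transcription factor of brainstem and spinal interneurons, fell from 1085 ± 59.9 to 228 ± 38.5 (SD, n = 2 each; log2 change -2.18 ± 0.18, SE; limma adjusted p = 5.14e-05). Hoxb3, a patterning gene of the hindbrain, fell by a log2 change of -1.12 and Nr4a2, a transcription factor of dopamine neurons, by -1.10. The 2 genes that rose were Th (1.32), the rate-limiting enzyme of dopamine synthesis, and Slc17a6 (0.64), a vesicular glutamate transporter. Camera gave an adjusted p of 5.58e-08 with the preset correlation, and adjusted p = 0.33 with an estimated correlation. Without the variance trend 9 fell.

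Lists of the forebrain also fell by camera's preset correlation. Among genes of the ganglionic eminences and GABAergic neurons, 10 of 22 fell, 1 rose and 11 did not pass (12 and 1 adjusted over the list alone), with a median log2 change of -0.26 (adjusted p = 0.000243, adjusted p = 0.458 with an estimated correlation). Ebf1 (-1.41), Zfhx3 (-1.22), Zfp503 (-0.80) and Isl1 (-0.71), transcriptional regulators with roles in striatal development, fell, and Npy, a neuropeptide of interneurons, rose (0.49; 0.38 and not past without knockout 1). The number that fell was 6 without control 1, 6 without knockout 2, 6 without the signal filter and 5 without the variance trend. Among forebrain regional genes, 7 of 19 fell, 1 rose and 11 did not pass (8 and 2 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00555, adjusted p = 0.469 with an estimated correlation). Gbx2 (-1.12), Barhl2 (-0.90) and Tcf7l2 (-0.83), expressed in the diencephalon, fell, and Emx1, a cortical transcription factor, rose (0.73; 0.67 and not past without knockout 1). Barhl2 did not pass without control 1 (-0.73), knockout 1 (-1.0) or knockout 2 (-0.81), and camera did not call the forebrain list without control 1 (adjusted p = 0.0505). The median of this list was -0.47 without control 2, -0.33 without knockout 1 and -0.29 without knockout 2, and 4 of its genes fell without the variance trend.

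The list of excitatory cortical neurons was not called by camera, while the directional test of fry passed. Of 21 genes, 7 rose, 7 fell and 7 did not pass (9 and 7 adjusted over the list alone). The median log2 change was 0.18, while the mean was -0.05 and the camera direction was down (adjusted p = 0.601), as was that of fry (adjusted p = 0.0202). The median was 0.10 without control 1, 0.01 without control 2, 0.07 without knockout 1 and 0.10 without knockout 2. Foxp2 (-1.52) and Lhx5 (-0.96), a marker of Cajal-Retzius cells that is also in the midbrain, hindbrain and spinal list, fell. Slc17a7 (1.23) and Slc17a6 (0.64) rose. With control 2, knockout 1 or knockout 2 left out, 4, 4 and 3 genes of the excitatory cortical list rose. With no variance trend 2 rose and 3 fell, and with no signal filter 3 rose. Slc17a7 lost its call without knockout 1 (1.25) or knockout 2 (1.20).

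**Figure D3:**
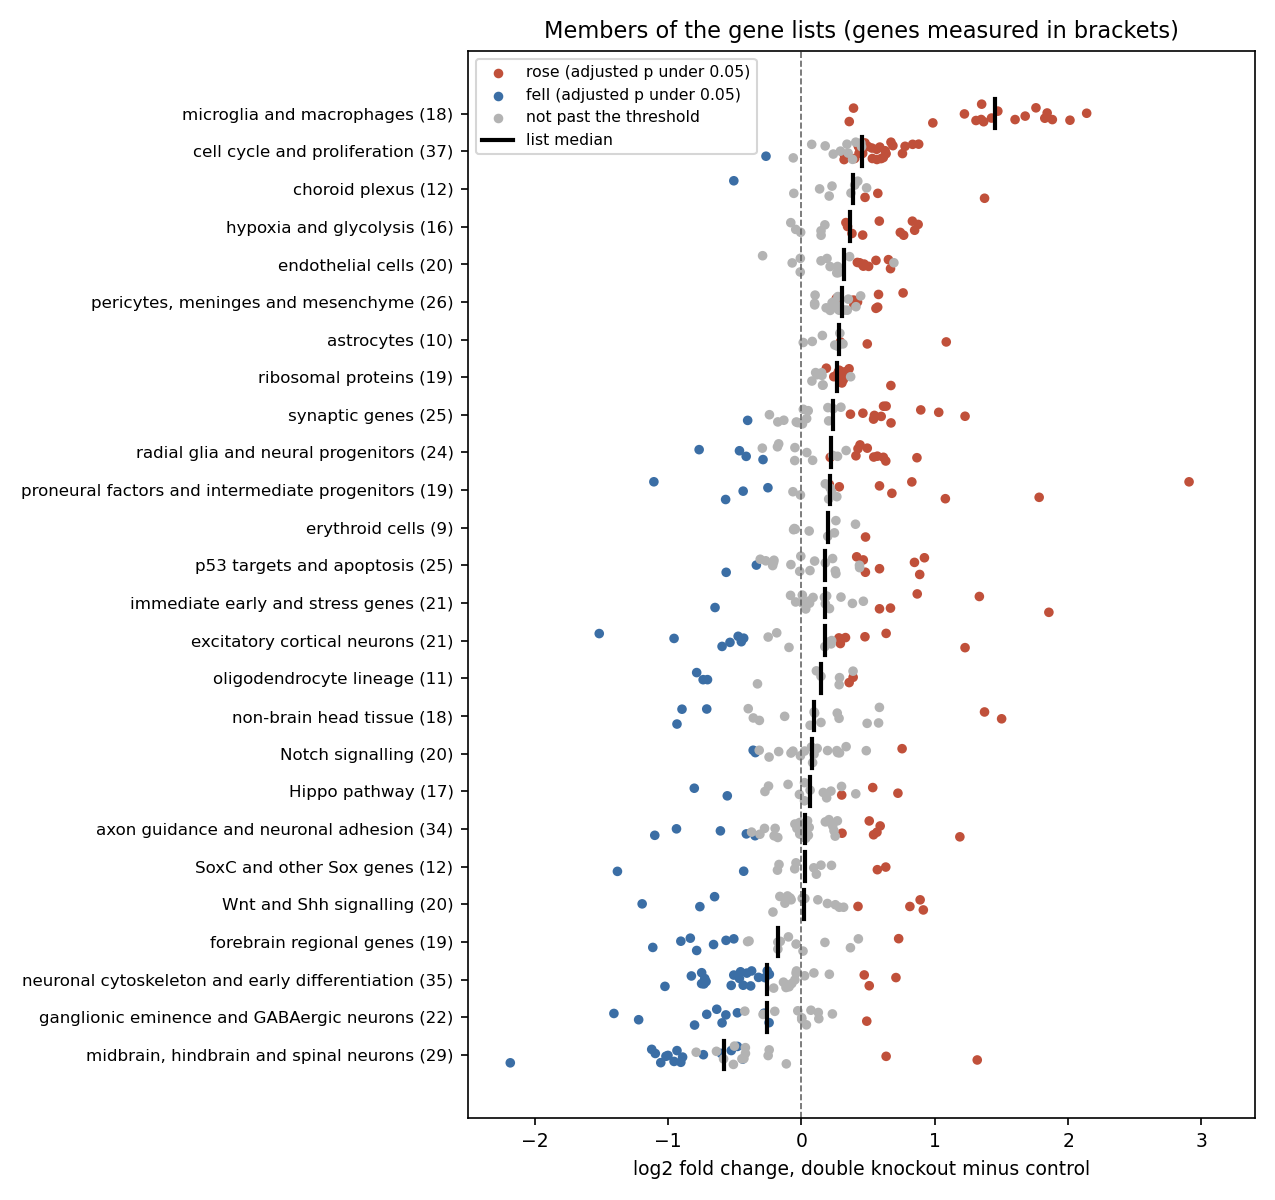
Log2 fold change (knockout minus control) of every measured member of the 26 gene lists with a set test, read at its brightest probe set; red rose, blue fell and grey did not pass an adjusted p of 0.05, black lines are list medians, and the vertical scatter within a list has no meaning. The microglia list has the highest median, 1.45, and the midbrain, hindbrain and spinal list the lowest, -0.58.

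Genes of microglia and macrophages showed the highest median of the 26 lists with a set test. All 18 measured rose (18 adjusted over the list alone), with a median log2 change of 1.45. C1qa went from 496.8 ± 6.51 to 2244 ± 70.9 (SD, n = 2 each; log2 change 2.14 ± 0.12, SE; limma adjusted p = 7.77e-06), and C1qb (2.01) and C1qc (1.88), the other chains of this complement component, and Apoe (1.84), a lipid carrier that astroglia also make, followed. Csf1r, the receptor on which microglia depend, went from 2621 to 7980 (log2 change 1.60). The smallest rises were those of Mrc1 (0.39) and Pf4 (0.36), and neither passed with any of the 4 arrays left out (0.29 to 0.49 and 0.30 to 0.42). Without control 1 or control 2, 17 of 19 measured rose, and without either knockout array 15 of 18. Camera gave an adjusted p of 6.76e-16 with the preset correlation, and adjusted p = 0.33 with an estimated correlation.

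Among pericyte, meningeal and mesenchymal genes 9 of 26 rose and 17 did not pass (9 adjusted over the list alone), with a median log2 change of 0.30 (camera adjusted p = 0.000438, adjusted p = 0.33 with an estimated correlation). Postn (0.76) and Col5a1 (0.58), matrix proteins, and Islr (0.57) rose. The count was 5 without control 1, 4 without knockout 2, 5 without the signal filter and 2 without the variance trend. Postn did not pass without knockout 2 (0.59), nor Col5a1 without control 2 (0.47), knockout 1 (0.48) or knockout 2 (0.68). Among endothelial genes 8 of 20 rose and 12 did not pass (8 adjusted over the list alone, median 0.32, camera adjusted p = 0.022, adjusted p = 0.458 with an estimated correlation), including Egfl7 (0.67) and Tek (0.65). This count was 0 without control 1, 0 without knockout 1, 2 without knockout 2, 2 without the signal filter and 1 without the variance trend, and camera did not call the list without control 1 (adjusted p = 0.127) or knockout 1 (adjusted p = 0.062). Egfl7 and Tek both lost their calls without control 1 (0.40 and 0.42), knockout 1 (0.63 and 0.60) or knockout 2 (0.71 and 0.71).

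Of 10 astrocyte genes 3 rose and 7 did not pass (6 adjusted over the list alone, median log2 change 0.28, camera adjusted p = 0.023, adjusted p = 0.458 with an estimated correlation). They were Aqp4 (1.09), a water channel, Aldoc (0.49) and Nfia (0.29). Aqp4 did not pass without knockout 1 (1.17) or knockout 2 (1.00), nor did Nfia without control 2 (0.19), knockout 1 (0.29) or knockout 2 (0.29), and Nfia averaged over its probe sets had a log2 change of -0.05. Only 1 astrocyte gene rose without knockout 2 or without the variance trend, 5 rose under median centring, the filter at the 60th percentile or robust eBayes and 6 with the replicate block, and camera did not call the list without control 1 (adjusted p = 0.127). Of 9 erythroid genes 1 rose, Car2 (0.48; not past without knockout 1 or knockout 2, at 0.45 and 0.51), and 8 did not pass (1 adjusted over the list alone, median 0.20, adjusted p = 0.478). Of 12 choroid plexus genes 3 rose, Rsph1 (1.37), Folr1 (0.57) and Clic6 (0.48), and Otx2 (-0.51) fell (6 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.0722). Folr1 did not pass without knockout 1 (0.56) or knockout 2 (0.58), nor Clic6 without knockout 2 (0.42). Of 11 oligodendrocyte-lineage genes Pdgfra (0.36) and Cnp (0.39) rose and Nkx2-2 (-0.79), Mbp (-0.74) and Bcas1 (-0.70) fell (2 and 3 adjusted over the list alone, median 0.15, mean -0.05, adjusted p = 0.627). None of these 5 passed without knockout 2 (0.28, 0.49, -0.82, -0.57 and -0.59). Pdgfra and Cnp did not pass with any of the 4 arrays left out, Nkx2-2 without control 1 (-0.60) or knockout 1 (-0.76), and Bcas1 without control 2 (-0.50) or knockout 1 (-0.82). Mbp averaged over its probe sets had a log2 change of 0.09, and Cnp and Pdgfra averaged so did not pass (0.23 and 0.32). Without the variance trend, the signal filter or knockout 1, 1 oligodendrocyte gene fell. With arrays left out, the oligodendrocyte median ranged from -0.12 (without knockout 1) to 0.28 (without knockout 2), the erythroid median fell to 0.06 without control 2 and 0.03 without knockout 2, and the choroid plexus median to 0.25 without control 2. Camera called the choroid plexus list without the signal filter (adjusted p = 0.0261), and 5 of its genes rose under median centring. Of 18 genes of head tissue outside the brain, Dct (1.50) and Col9a1 (1.37) rose and Pou4f1 (-0.93), Prox1 (-0.90) and Isl1 (-0.71) fell (2 and 3 adjusted over the list alone, median 0.10, camera direction down, adjusted p = 0.852). Prox1 did not pass without knockout 1 (-0.87) or knockout 2 (-0.92), and 4 of these genes rose without control 1 or under median centring. Their median was 0.16 without control 2 and 0.000456 without knockout 2. Pou4f1 is also in the midbrain, hindbrain and spinal list and Isl1 in the ganglionic eminence list. Their falls therefore cannot be placed in tissue outside the brain.

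Sex-linked transcripts differed within the control group. Xist, transcribed from the inactive X chromosome, read 166.4 on control 1, 25215 on control 2, 259.7 on knockout 1 and 1670 on knockout 2 at its brightest probe set. Eif2s3y, a gene of the Y chromosome, read 3484 on control 1, 43.5 on control 2, 3890 on knockout 1 and 3578 on knockout 2. None of the 4 sex-linked genes measured passed (0 adjusted over the list alone). All 4 passed under median centring and with the replicate number as a block. The prior degrees of freedom were 87.5 and 16.5 in those fits, against 8.33 in the main fit, which gives a gene's own spread less weight. Without control 1 the log2 changes were 5.98 for Eif2s3y, 4.67 for Kdm5d, 3.90 for Uty and -5.21 for Xist. Without control 2 the log2 change of Xist was 1.90 (adjusted p = 0.00502). Eif2s3y was thus low on control 2 alone, so the sex of the embryos appears unbalanced between the groups. With all genes of the X and Y chromosomes left out, 6130 probe sets changed, but this does not remove differences of sex in other genes. The fit without control 2 holds only arrays with a high Eif2s3y signal. All 6239 calls of the main fit still tested there kept their sign. All 6250 did so without control 1, where control 2 is the lone control. Those calls were made with the same arrays, so kept signs do not measure the effect of sex. The array control for 18S ribosomal RNA read 32281 and 23965 in controls and 17134 and 19178 in knockouts, and the ratio of 3′ to 5′ Actb signal lay between 1.41 and 1.48 on all 4 arrays.

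Genes of glycolysis and the hypoxia response rose. Of 16 measured, 10 rose and 6 did not pass (10 adjusted over the list alone), with a median log2 change of 0.36 (camera adjusted p = 0.000228, adjusted p = 0.458 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase (0.88), Aldoa (0.85) and Ldha (0.83), enzymes of glycolysis, and P4ha1 (0.77), a collagen hydroxylase, rose. Egln3 did not pass without knockout 1 (0.71), and the count was 6 without that array and 5 without the variance trend. Of 19 ribosomal protein genes, 11 rose and 8 did not pass (15 adjusted over the list alone, median 0.26, camera adjusted p = 4.54e-05, adjusted p = 0.33 with an estimated correlation). Rps6 (0.67), Rpl10a (0.36), Rps15 (0.32) and Rpl4 (0.32) had the largest rises. Under quantile normalization the list median was 0.14 and 8 genes rose (camera adjusted p = 0.0164 with the preset correlation). Rps6 did not pass without knockout 2 (0.54). This count was 5 without control 1, 6 without the signal filter and 0 without the variance trend.

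Immediate early and stress genes were not called as a list by camera (median log2 change 0.18, camera adjusted p = 0.0866). Of 21 measured, 5 rose, 1 fell and 15 did not pass (5 and 1 adjusted over the list alone). Those that rose were Fos (1.86), Egr1 (1.33), Jun (0.87), Ddit4 (0.67) and Btg2 (0.59), and Dusp1, a MAP kinase phosphatase, fell (-0.65). Camera called this list without control 2 (median 0.25, adjusted p = 0.0481) and without the signal filter (adjusted p = 0.0305), and Btg2 did not pass without control 2 (0.37), knockout 1 (0.58) or knockout 2 (0.59). Of 25 p53 target and apoptosis genes, 7 rose, 2 fell and 16 did not pass (7 and 3 adjusted over the list alone, median 0.18, adjusted p = 0.601). Sesn2 (0.92), Ccng1 (0.89) and Pmaip1 (0.85) had the largest rises, and Bcl2 (-0.56), an inhibitor of apoptosis, and Plk2 (-0.34) fell. Sesn2 did not pass without knockout 2 (0.55), Pmaip1 without control 1 (0.65), knockout 1 (0.96) or knockout 2 (0.74), and Plk2 without control 2 (-0.23), knockout 1 (-0.34) or knockout 2 (-0.34). The number that rose was 4 without control 1, 3 without knockout 1, 4 without the signal filter and 2 without the variance trend, and the number that fell was 1 without control 2 and 1 without knockout 1. The p53 list median was 0.10 without control 1.

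Lists of signalling pathways were not called by camera. Of 20 Notch genes, Mfng (0.75), a glycosyltransferase that modifies Notch, rose and Rbpj (-0.36) and Maml1 (-0.35) fell (1 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.928). Rbpj did not pass without control 2 (-0.29) or knockout 2 (-0.22), nor Maml1 with any of the 4 arrays left out (-0.37 to -0.32), and 2 Notch genes rose without control 1. Other probe sets of Rbpj (-0.15 and 0.04) and Maml1 (-0.14) did not pass, nor did their averages over probe sets (-0.16 and -0.24). Of 20 Wnt and Shh genes, Dkk3 (0.91), Fzd5 (0.89), Wnt7b (0.81) and Gli3 (0.42) rose and Sp5 (-1.19), Lgr5 (-0.76) and Lef1 (-0.65) fell (5 and 3 adjusted over the list alone, median 0.02, adjusted p = 0.928). Fzd5 did not pass without knockout 1 (0.79), Lef1 without knockout 2 (-0.44), Gli3 without control 1 (0.35), knockout 1 (0.48) or knockout 2 (0.37), and Lgr5 with any of the 4 arrays left out (-0.80 to -0.73). Of the Wnt and Shh genes 2 rose without knockout 1, and 1 fell without knockout 2 or with the filter at the 60th percentile. Lef1 averaged over its probe sets did not pass (-0.47). With arrays left out the Notch median ranged from 0.03 (without control 2) to 0.12 (without control 1), and the Wnt and Shh median from -0.04 (without control 2) to 0.10 (without control 1).

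Of 17 Hippo pathway genes, Ccn1 (0.72), Wwtr1 (0.53) and Tead1 (0.30) rose and Amotl2 (-0.80) and Amotl1 (-0.56) fell (3 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.928). Tead2, a transcription factor of this pathway, had a log2 change of -0.25 ± 0.13 (SE, adjusted p = 0.198). Amotl1 did not pass without knockout 1 (-0.44), Ccn1 without control 2 (0.64), knockout 1 (0.58) or knockout 2 (0.87), and Tead1 with any of the 4 arrays left out (0.26 to 0.35). The other probe sets of Ccn1 (0.34, 0.33 and 0.09) did not pass, nor did the average over them all (0.37). Only 1 Hippo gene rose without control 2, knockout 1, knockout 2 or the signal filter. The Hippo median was 0.20 without control 1 and 0.14 without knockout 2. Of 34 genes of axon guidance and neuronal adhesion, 6 rose, 5 fell and 23 did not pass (6 and 5 adjusted over the list alone, median 0.03, camera direction down, adjusted p = 0.928). Cntn1 (1.19), a neuronal adhesion molecule, had the largest rise, and Efna2 (-1.10), Plxnb1 (-0.94), Robo1 (-0.61), Chl1 (-0.41) and Ephb1 (-0.35) fell. Ephb1 did not pass without control 2 (-0.21), knockout 1 (-0.35) or knockout 2 (-0.35). The median of this list ranged from -0.000131 (without control 2) to 0.08 (without knockout 2), and 2 of its genes fell without the variance trend. In the list of 12 Sox genes, Sox3 (0.63) and Sox9 (0.57) rose and Sox11 and Sox5 (-0.43) fell (2 and 2 adjusted over the list alone, median 0.03, mean -0.04, adjusted p = 0.601). Sox9 did not pass without knockout 1 (0.46), nor Sox5 without control 2 (-0.34), knockout 1 (-0.42) or knockout 2 (-0.44). The Sox list median ranged from -0.06 (without knockout 1) to 0.11 (without control 1).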

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

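Leaving out genes of the sex chromosomes was chosen after the data were seen, as were the list counts given with single arrays left out. The other settings, with each array left out in turn among them, were planned. Of the 6277 calls, 2937 were kept in eBayes without trend and 2964 (without knockout 1) to 4539 (without control 2) with an array left out. The count of changed probe sets was 3114 in eBayes without trend (1471 rose and 1643 fell). With single arrays left out it ranged from 3132 to 5422, with 1458 to 2611 that rose and 1674 to 2811 that fell; fewer arrays leave 1 residual degree of freedom. In the other settings, apart from the block below, it was 4317 (no filter) to 6536 (robust eBayes), and 8520 at a threshold of 0.1. Median centring gave 6417, 55.8% of which rose against 50.2% in the main setting. Replicate numbers did not pair the arrays: the correlation of deviations of same-numbered arrays was 0.0028, and with the number as a block 6844 changed. The other 2 splits of the arrays gave 0 and 0 calls in limma (132 and 155 at an unadjusted p under 0.05), and 3 splits are too few for a share under 0.05. Each of those 2 splits puts a control and a knockout in both arms. The genotype difference then adds to the residual spread, so few calls could be made and the splits decide nothing. With arrays left out, the log2 change of Sox4 at 1455867_at ranged from -1.19 to -1.0, and list medians ranged from 0.20 to 0.31 (proneural factors), -0.47 to -0.16 (forebrain regional genes), 0.23 to 0.28 (astrocytes) and 0.30 to 0.37 (endothelial cells); each lost its call without at least 1 array. The proneural list (0.21) was also not called under quantile normalization, nor astrocytes under median centring (0.32) or the filter at the 60th percentile (0.27). Averaging probe sets reversed Nfia (-0.0472) and Mbp (0.0939), whose probe sets disagree. It ended 11 calls, among them Nes (0.22), Ccn1 (0.37), Rbpj (-0.16), Maml1 (-0.24), Cnp (0.23), Cntn2 (0.31), Elavl2 (-0.19), Mcm7 (-0.20), Lef1 (-0.47) and Pdgfra (0.32), and Sox12 rose (0.36). Without the filter camera also called the lists of choroid plexus and of immediate early and stress genes, the latter also without control 2. The cause of the other changes was not tested. Of 152 other named genes that were called, over 2246 combinations with a setting, the call and direction were kept in 2005, lost in 239 and reversed in 2. The losses were 50 in eBayes without trend, 46 without knockout 2, 44 without knockout 1, 33 with no filter, 23 without control 2 and 21 without control 1. Dim signals near the pseudocount of 16 have understated changes.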

Other observations

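The families, genes and tests of this part were all chosen after the results were seen. Clustered protocadherins of the beta group, adhesion molecules of neurons, fell together. All 9 Pcdhb genes that passed the signal filter fell, with a median log2 change of -1.42, from Pcdhb16 (-2.02) and Pcdhb7 (-1.93) to Pcdhb3 (-1.06), and these paralogs can share signal. Without the filter 22 were measured and 10 fell (median -1.17). Pcdhgc4, of the neighbouring gamma group, did not pass (-0.37; limma adjusted p = 0.152). Of 196 families of at least 8 genes defined by a shared symbol stem, 8 passed camera with the preset correlation and 0 with an estimated correlation. The adjusted p of Pcdhb was 1.556e-07, or 0.986 with an estimated correlation. Besides Pcdhb and Zfp, those that passed were Kdm, with a median of -0.30, and Rps, Rpl, Ndufa, Emc and Ndufb, with medians of 0.16 to 0.29. Without the variance trend 1 Ndufa gene and 0 Ndufb genes rose. With single arrays left out, 6 (without knockout 1) to 9 Pcdhb genes fell. Zinc finger genes named Zfp had a median of -0.28, and 77 of 300 fell while 8 rose (adjusted p = 8.94e-10, or 0.986 with an estimated correlation). The number that fell was 37 without knockout 1 and 35 without the variance trend.

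Some single genes were also picked. St8sia2, which makes polysialic acid on neural cell adhesion molecule, fell from 5502 ± 303 to 1960 ± 114 (SD, n = 2 each; log2 change -1.48 ± 0.10, SE; limma adjusted p = 1.55e-05). St6gal2, a sialyltransferase, fell by a log2 change of -1.54 and St6gal1, its paralog, by -1.36. Cd24a, a sialylated surface protein of young neurons, fell at its brightest probe set by -0.74. Tfap2b (-1.70) and Ebf3 (-1.37), transcription factors, fell. Xist on knockout 2 read 1670, or 6.62% of the signal on control 2, beside a Y-linked Eif2s3y signal of 3578.

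The Sox4 probe sets moved in opposite directions. Of the 12 tested Sox4 and Sox11 probe sets, 10 were lower on both knockout arrays and 2 were higher. This argues against exchanged array labels as far as the probe sets that fell lie in the deleted part, which is unknown. Saturation of the brightest Sox4 probe set stays open. Of 93 other probe sets at least 90% as bright in controls 4 fell, the largest by -0.74 (Cd24a), but this does not show whether that probe set was compressed. A further candidate explanation that stays open is RNA from the recombined allele, detected by probes outside the deleted part, and probe sequences would be needed to test it.

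All 18 microglia and macrophage genes rose. A lower share of neurons would raise other cell types alike, yet the microglia median exceeded the highest of the endothelial, mesenchymal and erythroid medians by 1.13 (log2). A permutation over genes set the microglia median against that of those other lists pooled. It gave p = 1e-04, the smallest that 9999 permutations can give. Genes read on the same arrays are not independent, so this p describes the listed genes only. Blood rich in red cells is argued against as the source, since the microglia median lay 1.25 above the erythroid median and the highest erythroid change was 0.48. The globin Hbb-y, at 33842 in controls and 35236 in knockouts, may be too bright to show a rise. White cells of the blood were not tested, since erythroid genes do not mark them. A chi-square of 261.3 on 17 degrees of freedom against a single factor for every member decides nothing, since probe sets differ in compression and other cells make some of these transcripts. More microglia or other macrophages, such cells in a changed state, or both, may underlie the rise, and these were not told apart in whole-brain RNA.

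Genes of the midbrain, hindbrain and spinal cord fell. A smaller share of caudal tissue in the knockout samples, through dissection or growth, could give this. All 12 measured Hox genes had negative values (median -0.53, and 5 fell). Most of them are members of the midbrain, hindbrain and spinal list, so their values restate its fall and are no separate check. A smaller share of caudal tissue stays open for them. Genes of the ganglionic eminences do not decide whether it accounts for falls in the forebrain. Of 5 genes, 3 fell, Dlx5 (-0.57), Dlx6 (-0.64) and Lhx6 (-0.48), while Dlx1 (0.23) and Dlx2 (0.04) did not pass. Each of those 3 calls was lost without knockout 2 (-0.54, -0.52 and -0.34), those of Dlx6 and Lhx6 without control 1 (-0.54 and -0.38), and that of Dlx6 without knockout 1 (-0.75). Without knockout 2, Dlx1 rose (0.55, adjusted p = 0.0372). Without the signal filter or the variance trend only Dlx5 fell. An effect of the knockout itself also stays open and was not tested, since no table shows where Brn4::Cre acted.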
